A study of Mus musculus with 6 samples.

How the data were processed

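Total RNA of cochleae from postnatal day 3 mice was sequenced in 6 libraries, 3 from Plscr5 knockout and 3 from wild-type mice, grouped by the genotype in the labels. The labels number the libraries 1 to 3 within each genotype and do not say that each came from a separate animal or how many cochleae it pooled, so p-values measure only the spread between these libraries, part of which may be technical. The extraction text of the labels speaks of a Pou4f3 heterozygous line that no library lists, and the genotype field was used for all groups.

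The deposited values are in TPM (transcript abundance scaled by transcript length to a constant total): in each library they sum to 1000000 and are written with 2 decimals. This unit was read from the values. This scaling keeps no read depth, and no counting interval or detection floor can be given. The submitters' processing notes list DESeq2 and the genome build mm8, with no role given, and the aligner, the quantifier and the annotation are not given in the sources used here. The files hold 55416 Ensembl gene IDs and 353 IDs of the form MSTRG plus a number. Symbols, biotypes, transcript lengths and gene neighbourhoods came from GENCODE M21 (GRCm38), which gave a symbol to 52083 IDs. Because that build differs from the one in the processing notes, no coordinates are given. An exact 0 can be a failed estimate, since 7 protein-coding genes outside the Y chromosome were at 0 in 1 or more libraries and above 10 TPM in another, so a gene at 0 is described as listed at 0.

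Tests for read counts had been chosen first, with a rule for normalized values should the files hold those, and that rule was used because the values are TPM. Features with at least 1 TPM in at least 3 libraries were kept, which left 17097, of which 16744 had a symbol and 14240 were protein-coding. Values were transformed to log2(TPM + 1), with a pseudocount of 1. Genotype was tested with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance moderation, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. No filter on fold size was applied.

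The gene lists were tested with camera from limma at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. There were 32 lists, covering the hair bundle, hair cell identity, the tectorial membrane, neurons, Schwann cells, osteoblasts, cell division, oxidative phosphorylation, mitochondrially encoded genes, scramblases and flippases, and other cell types, signalling and stress responses. All 32 had at least 3 tested members, 549 distinct genes in total. camera compares a list with the other genes. fry tests whether a list's genes move one way on balance or, in its mixed form, change in either direction, and compares them with nothing else. The 10 lists described gene by gene were chosen after the list results were seen. A nerve score was the mean over the neuronal and Schwann cell lists of log2(TPM + 1) after centring each gene.

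The genes named were Plscr5 and the other Plscr genes; among genes past the threshold, with no overlap between groups and a mean of at least 1 TPM in the higher group, up to 10 per direction with the largest fold change, predicted genes and pseudogenes being counted but not named while others remained; where none qualified in a direction, the 5 with the smallest p in that direction, as values; up to 4 members with the smallest p of each list described; and the 5 genes with the smallest p overall. Here 0 genes qualified on the higher side and 2 on the lower. Fscn2, Mgp, mt-Nd4, Rpl37 and the second Chtf8 feature were named after their values were seen. The groups, the tests, the lists, the naming rule and the alternatives other than those named below as added were fixed before the data were examined.

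The fit was tested on simulated data with the means and residual spreads of the 17097 real features, in which 200 features with a mean log2(TPM + 1) above 2 were changed. At 1.5-fold 26 of 66 changed features passed (39.4%), at 2-fold 53 of 68 (77.9%) and at 4-fold 59 of 66 (89.4%), with 3 unchanged features passing. The simulation drew genes independently with normal errors, which real libraries need not follow. A simulated list of 30 genes lowered to 0.9 of their level passed camera (adjusted p = 2.28e-06), and 0 of 32 unchanged lists did. In the 7 real lists that passed camera, the estimated inter-gene correlation ran from 0.10 (osteoblast) to 0.70 (cell division). Because the simulated genes were independent, the simulation cannot tell how often unchanged lists pass at the preset correlation of 0.01 in these libraries.

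Alternatives were other scalings, filters, pseudocounts and variance settings, the removal of haemoglobin and mitochondrial genes, a sex make-up covariate, a block on replicate number and each library left out in turn. A higher filter, the nerve score as a covariate, removal of the transcript length trend and a restriction to protein-coding genes were added after the data were seen. The highest share of identical values between 2 libraries was 0.386%, so no library was treated as a duplicate. Figures were drawn with matplotlib 3.10.9.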

Results

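RNA-seq of the whole mouse cochlea, the hearing organ of the inner ear, was compared between Plscr5 knockout and wild-type mice on postnatal day 3, with 3 libraries per genotype. Plscr5 belongs to the phospholipid scramblases, a family of membrane proteins named for the movement of phospholipids between the leaflets of a membrane. The comparison asked which transcripts of the early postnatal cochlea differed when this gene was disrupted. Each library held values for 55769 features in TPM, a transcript abundance scaled by transcript length to a constant total, and 17097 features were tested. Sequencing depth is unknown, because TPM values keep no read totals. Across tested genes, pairs of libraries correlated with a Pearson r between 0.9635 and 0.9852, and genes are not independent replicates. Errors below are SD over 3 libraries unless named otherwise, and log2 fold changes are knockout minus wild type on the log2(TPM + 1) scale, which understates the change of low genes.

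Plscr5 (ENSMUSG00000095654) was lower in all 3 knockout libraries, at 4.30, 3.69 and 5.01 TPM, than in the 3 wild-type libraries, at 14.53, 12.42 and 9.27 TPM. The mean was 4.33 ± 0.66 TPM in the knockout and 12.1 ± 2.6 TPM in the wild type, so that 35.9% of the wild-type level remained. The labels do not say which part of the gene was altered. The other scramblase genes did not differ detectably. Plscr3 stood at 79.6 ± 3.1 TPM in the knockout and 78.8 ± 11.05 TPM in the wild type, with log2 fold changes of 0.02 for Plscr3, 0.05 for Plscr1, -0.14 for Plscr2 and 0.03 for Plscr4. In the limma fit the log2 fold change of Plscr5 was -1.28 (SE 0.18, 95% confidence interval -1.70 to -0.86), with an unadjusted p of 0.000119 that ranked 7 among the tested genes and an adjusted p of 0.29, so it did not pass the threshold. A two-sided exact permutation test of the 6 Plscr5 values gave p = 0.1, the smallest that 3 libraries against 3 can give. Over the wider scramblase and flippase list, 15 of 34 tested members were higher and 19 lower, with a median log2 fold change of -0.03 (camera adjusted p = 0.477). Its members with the smallest p were Tmem30b (log2 fold change -0.15), a subunit of flippases, Anxa5 (-0.09), which binds phosphatidylserine, Atp11a (-0.13) and Tmem63c (0.40), and none of them passed the threshold.

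**Figure D1:**
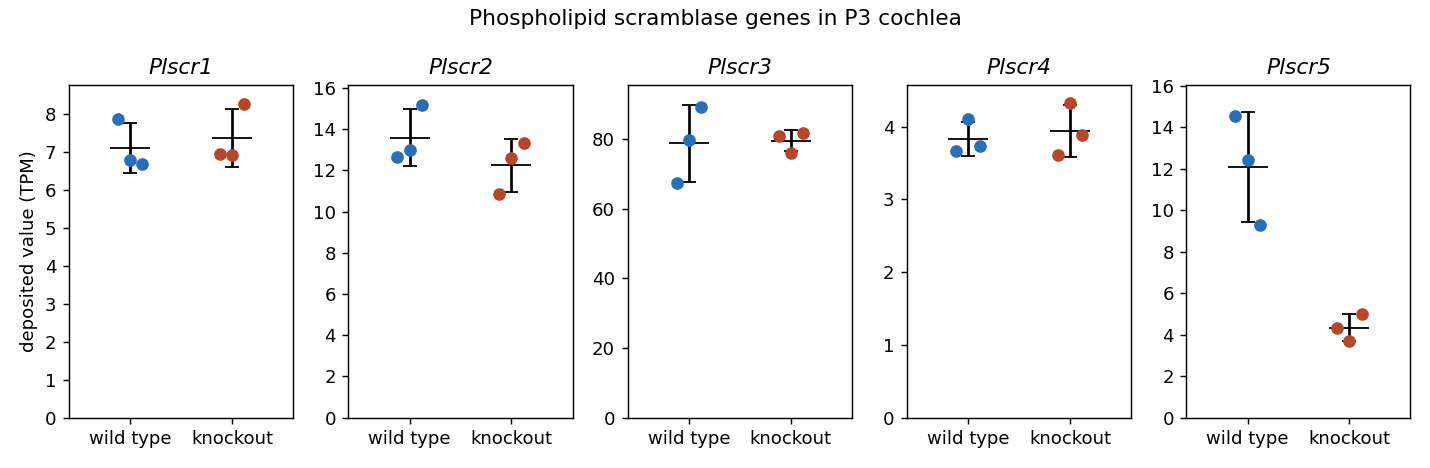
TPM of the 5 Plscr genes, 1 panel per gene with its own axis from 0. Points are the 3 wild-type (blue) and 3 knockout (red) libraries, and bars are the mean ± SD. The knockout Plscr5 points, at 3.69 to 5.01 TPM, lie below the wild-type points, at 9.27 to 14.53 TPM, and the points of the other 4 genes overlap.

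After adjustment 2 features other than Plscr5 passed the threshold as lower in the knockout, and 0 passed as higher. The mitochondrially encoded mt-Nd4l (ENSMUSG00000065947), a subunit of respiratory complex I, fell from 1166 ± 73 TPM in the wild type to 704 ± 16 TPM in the knockout, with no overlap between the groups (log2 fold change -0.72, SE 0.06, limma adjusted p = 0.0163). ENSMUSG00002074928, to which the annotation used here gives no symbol, was listed at 0 in all 3 knockout libraries and at 23.09, 13.16 and 10.24 TPM in the wild-type libraries. The limma adjusted p of ENSMUSG00002074928 was 0.00887. The gene mt-Nd4, which overlaps mt-Nd4l on the mitochondrial genome, stood at 4090 ± 253 TPM in the knockout and 4196 ± 66 TPM in the wild type (log2 fold change -0.04), and mt-Nd3 had a log2 fold change of -0.33 (SE 0.11) that did not pass. The split of reads between mt-Nd4l and its overlapping neighbour is not known, so its value is uncertain. Among the members of the mitochondrially encoded list with the smallest p were mt-Co2 (0.66) and mt-Co3 (0.64). When single libraries were left out, mt-Co2 ranged from 0.12 to 1.03 and mt-Co3 from -0.10 to 1.11. Over the 13 mitochondrially encoded genes, 7 were higher and 6 lower, with a median log2 fold change of 0.01 (camera adjusted p = 0.32). The fry test for change in either direction gave this list an adjusted p of 0.00616, the only one of 32 lists to pass, and mt-Nd4l was its 1 member past the threshold, both over all genes and adjusted over the list alone.

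Among the 5 genes with the smallest p on the higher side, none passed the threshold. Crygn, a member of the crystallin family, was listed at 8.07, 7.52 and 6.70 TPM in the knockout and 0, 0.39 and 1.01 TPM in the wild type (log2 fold change 2.58, SE 0.26, limma adjusted p = 0.0541). Rpl37rt, a transcribed processed copy of the ribosomal protein gene Rpl37, stood at 490.5 ± 34 and 326 ± 10 TPM (log2 fold change 0.58), while Rpl37 itself had a log2 fold change of 0.03, and reads can be shared between the 2 copies. Of 2 overlapping features that both carry the name Chtf8, ENSMUSG00000117748 stood at 9.26 ± 1.38 and 3.09 ± 0.49 TPM and ENSMUSG00000046691 at 69.5 ± 9.6 and 70.4 ± 9.9 TPM in knockout and wild type. Gm48349, a processed pseudogene, stood at 4.93 ± 0.87 and 1.83 ± 0.30 TPM, and the noncoding Gm14235 was listed at 1.30, 1.12 and 1.49 TPM in the knockout and at 0 in all 3 wild-type libraries.

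By limma, 684 of 17097 features had an unadjusted p under 0.05, of which 368 were higher and 316 lower in the knockout. That is a share below 0.05, the share that chance gives at this threshold. Splits of the libraries into 3 and 3 that do not follow genotype gave from 311 to 2718 such features. Over the alternatives the genotype count ranged from 354 without knockout replicate 2 to 1250 with the replicate block. Without the variance trend limma passed 0 features after adjustment. The groups did not overlap at 1596 features, or 9.34%, where chance gives 10%. The 95% confidence interval lay within 2-fold in either direction for 15649 features (91.5%). The mt-Nd4l log2 fold change stayed between -0.77 and -0.68 whichever library was left out, but the calls did not all hold: leaving out knockout replicate 1, knockout replicate 3 or wild type replicate 1 left 0 lower features, leaving out knockout replicate 2 kept the unnamed feature but not mt-Nd4l, and leaving out wild type replicate 2 or 3 left 1, mt-Nd4l, since the unnamed feature then fell below the filter. mt-Nd4l passed in 9 of 19 alternative settings (adjusted p from 0.00904 to 0.318) and the unnamed feature in 8 of 15 (adjusted p from 0.00238 to 0.112).

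Genes of the hair bundle, the actin-based organelle with which hair cells detect sound, were slightly lower in the knockout as a group. Of 34 tested members of this list, 33 had a negative log2 fold change, with a median of -0.16, which is a change of -10.7% in TPM + 1, and at 9 of them all knockout values lay below all wild-type values. Ush1c, a scaffold of the tip-link complex, stood at 124 ± 3 TPM in the knockout and 143 ± 13 TPM in the wild type. The tip-link cadherin Pcdh15 stood at 7.85 ± 0.76 and 9.77 ± 0.71 TPM, the actin bundler Pls1 at 45.0 ± 1.1 and 51.9 ± 4.3 TPM, and the unconventional myosin Myo3b at 6.52 ± 0.22 and 8.07 ± 0.08 TPM. Fscn2 was the 1 member with a positive log2 fold change, of 0.08. The list passed camera with its preset correlation (adjusted p = 5.2e-08) and lost that call with an estimated correlation (adjusted p = 0.571, unadjusted p = 0.0344). 0 members passed over all genes, and 0 adjusted over the list alone.

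**Figure D2:**
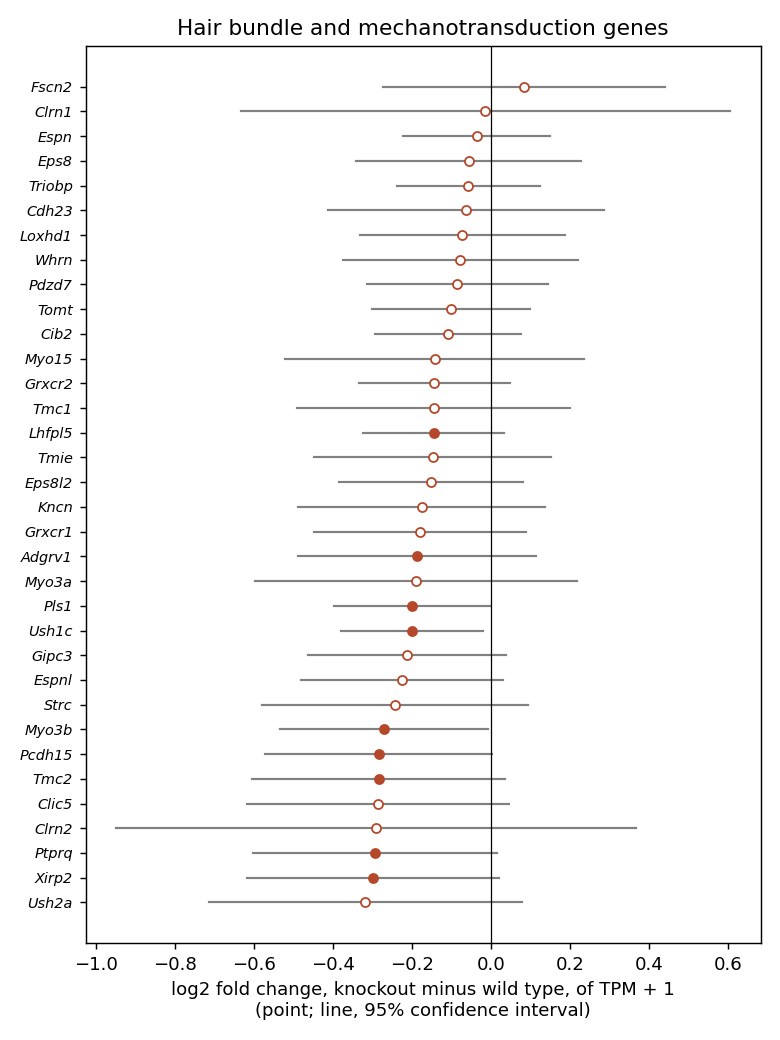
Log2 fold change, knockout minus wild type on the log2(TPM + 1) scale, of the 34 tested hair bundle and mechanotransduction genes, ordered by size, with 95% confidence intervals as lines. Filled points are the 9 genes at which all knockout values lay below all wild-type values. Points of 33 genes lie below 0 and that of Fscn2 above it.

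Genes that mark hair cells as a cell type did not pass as a list. Of 23 tested members, 14 were lower and 9 higher, with a median log2 fold change of -0.06 (camera adjusted p = 0.175, and 0.571 with an estimated correlation). This median ranged from -0.12 to -0.02 when single libraries were left out. Kcna10, a potassium channel gene, stood at 15.0 ± 1.7 TPM in the knockout and 20.3 ± 2.3 TPM in the wild type, Smpx at 62.7 ± 4.7 and 72.7 ± 5.8 TPM, and Rbm24 at 35.9 ± 3.2 and 42.4 ± 6.0 TPM. Pvalb, which neurons also express, stood at 165 ± 21 and 109 ± 47 TPM. Its log2 fold change of 0.70 was 0.27 without wild type replicate 3 and 0.08 with the nerve score covariate. None of these 4 genes passed the threshold. The ribbon synapse list had a median log2 fold change of 0.08 (camera adjusted p = 0.204), and the supporting cell list one of -0.06 (camera adjusted p = 0.196).

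Genes of the tectorial membrane, the extracellular matrix that lies over the hair cells, were lower as a group. Of 10 tested members 9 were lower, with a median log2 fold change of -0.20 (camera adjusted p = 8.8e-05, and 0.571 with an estimated correlation). Tectb, which encodes a tectorin, stood at 3718 ± 122 TPM in the knockout and 4337 ± 383 TPM in the wild type, Epyc at 892 ± 22 and 1030 ± 67.1 TPM, Otoa at 599.6 ± 26 and 699 ± 66 TPM, and Otogl at 72.2 ± 1.3 and 85.0 ± 9.6 TPM. None of these passed singly, over all genes or adjusted over the list alone. Without wild type replicate 3 the list median was -0.07 and the list no longer passed camera (adjusted p = 0.143, in a range of 1.05e-06 to 0.825 over 20 alternatives), nor did it with the nerve score covariate (0.825).

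Neuronal and Schwann cell genes were higher in the knockout as groups, and 1 wild-type library stood apart in both. Of 26 neuronal genes 21 were higher, with a median log2 fold change of 0.65 (camera adjusted p = 5.72e-06), and of 21 Schwann cell and myelin genes 19 were higher, with a median of 0.64 (camera adjusted p = 1.05e-07). With an estimated correlation both had an adjusted p of 0.571. Wild type replicate 3 had list medians of -1.17 for neuronal and -1.24 for Schwann cell genes relative to the mean of all libraries, and the other 5 libraries lay between -0.02 and 0.64. Among those 5 the genotypes overlapped. For neuronal genes knockout replicate 3 stood at 0.12 and wild type replicate 2 at 0.24, and for Schwann cell genes they stood at 0.0776 and 0.0779. Knockout replicate 1 was highest in both lists, at 0.55 and 0.64. Without wild type replicate 3 the medians were 0.21 and 0.23, and both lists still passed camera (adjusted p = 0.00249 and 0.000535). Both passed in 19 of 20 alternatives, with adjusted p from 1.12e-09 to 0.00249 and from 1.75e-10 to 0.000666, and the exception was the nerve score covariate, which is built from these genes and so removes their difference. The myelin protein gene Mag stood at 14.6 ± 5.0 TPM in the knockout and 7.83 ± 4.50 TPM in the wild type, with 2.76 TPM in wild type replicate 3. Gldn, Pllp and Fa2h had log2 fold changes of 0.51, 0.37 and 0.73. When single libraries were left out, Gldn ranged from 0.28 to 0.67, Pllp from 0.20 to 0.51 and Fa2h from 0.31 to 0.97. The neuronal members with the smallest p went both ways: the calcium-binding protein gene Calb1 had a log2 fold change of -0.26 and the synaptic vesicle gene Syt1 one of -0.15, whereas Uchl1 had 0.17 and the sodium channel gene Scn9a 0.63. Scn9a ranged from 0.27 to 0.83 when single libraries were left out. 0 members of either list passed, over all genes or adjusted over the list alone.

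**Figure D3:**
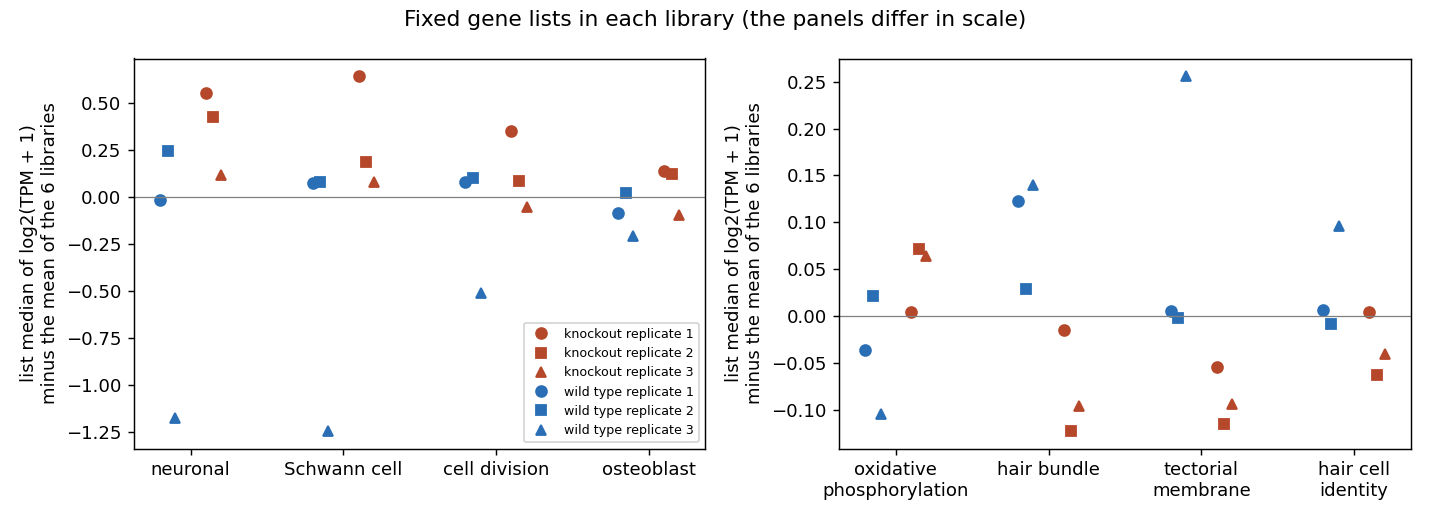
Median over each gene list of log2(TPM + 1) minus the mean of the 6 libraries, for the 7 lists that passed camera with its preset correlation and for hair cell identity, with 1 symbol per library (red, knockout; blue, wild type) and a different vertical scale in each panel. Wild type replicate 3 lies at -1.17 for neuronal and -1.24 for Schwann cell genes, below all other libraries. For the hair bundle list the 3 knockout libraries, at -0.12 to -0.01, lie below the 3 wild-type libraries, at 0.03 to 0.14.

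Genes of cell division, bone formation and oxidative phosphorylation were also higher on balance, with wild type replicate 3 lowest in each. Of 24 cell division genes 20 were higher (median log2 fold change 0.24, camera adjusted p = 6.65e-05, and 0.571 with an estimated correlation), among them Plk1 (0.43), Ccna2 (0.36), Ccnb2 (0.48) and Aurkb (0.48). Of 11 osteoblast genes 10 were higher (median 0.20, camera adjusted p = 0.00902, and 0.571 with an estimated correlation), with values of 0.35 for Ifitm5, 0.22 for Col1a1, 0.95 for Spp1 and 0.30 for Phex. When single libraries were left out, Ifitm5 ranged from 0.32 to 0.38, Col1a1 from 0.08 to 0.35, Spp1 from 0.26 to 1.40 and Phex from 0.13 to 0.47. Of 41 nuclear genes of oxidative phosphorylation 38 were higher (median 0.09, camera adjusted p = 6.36e-08, and 0.571 with an estimated correlation), with values of 0.17 for Uqcrc1, 0.27 for Cox5a, 0.15 for Ndufa8 and 0.16 for Cox4i1. 0 members of these 3 lists passed, over all genes or adjusted over the list alone. Without wild type replicate 3 the cell division median was 0.02 (camera adjusted p = 0.596, in a range of 4.05e-08 to 0.596 over 20 alternatives) and the osteoblast median 0.13 (0.0527, in a range of 0.00213 to 0.281), so that both calls ended. The osteoblast list passed in 16 of 20 alternatives, and its call also ended without knockout replicate 1, at a median of 0.12 (adjusted p = 0.0576 in that setting), with the filter at 5 TPM (0.0532) and with the nerve score covariate (0.281). That covariate also ended the calls of the cell division list, at a median of -0.12 (camera adjusted p = 0.281), and of the oxidative phosphorylation list, at 0.04 (0.0654). Without wild type replicate 3 the oxidative phosphorylation median was 0.05 (0.00672, in a range of 8.53e-10 to 0.0654).

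In all, 7 of 32 lists passed camera with its preset correlation, 5 higher and 2 lower in the knockout, 0 passed with an estimated correlation and 0 passed the directional fry test. The 25 other lists had camera adjusted p values from 0.052 to 0.905. The smallest belonged to the stria vascularis and ion transport list, with 16 of 21 members lower and a median log2 fold change of -0.09, and that list passed in 6 of 20 alternatives (adjusted p from 0.00312 to 0.829). Red blood cell genes had a median of -0.38 (camera adjusted p = 0.0835) and passed in 3 of 20 alternatives, among them without knockout replicate 2 (adjusted p = 6.84e-11, in a range up to 0.737). Genes of the unfolded protein response had a median of -0.25 (camera adjusted p = 0.101) and passed in 7 of 20 alternatives, among them without knockout replicate 1 (0.000249) and without wild type replicate 3 (0.000535), in a range of 8.61e-06 to 0.854. Among otic fibroblast genes (median 0.02, camera adjusted p = 0.16), Mgp, an inhibitor of calcification, stood at 119 ± 3 TPM in the knockout and 92.2 ± 7.9 TPM in the wild type (log2 fold change 0.37). Mgp passed adjusted over the list alone (limma adjusted p = 0.0258), as no other member did, but not over all genes (limma adjusted p = 0.989).

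Genes near Plscr5 did not stand out. Of the 2 passing features, mt-Nd4l alone had a position in the annotation, so the share within 10 Mb of Plscr5 was 0 of 1 (two-sided Fisher's exact p = 1), a test that says nothing at this number. Of 97 positioned genes with an unadjusted limma p under 0.01, 0 lay within 10 Mb of Plscr5 and 2 within 20 Mb. Among all 16746 positioned tested genes other than Plscr5, 120 lay within 10 Mb and 346 within 20 Mb. Few low-p genes could fall there by chance, so the count of 0 also says little.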

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

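The filter at 5 TPM, the nerve score covariate, the length trend removed and protein-coding genes only were chosen after seeing the data. Of 96 checks on the main results 69 held, 8 moved up and 19 down. Of 978 checks on named genes 950 kept direction and call, 17 lost and 4 gained a call and 7 changed sign. Only mt-Nd4l (9 of 19 kept) and the unnamed feature (8 of 15) had one to lose. Of 199 checks on described lists 181 kept sign and call, 9 lost only their call and 9 changed sign. Of those 9, 2 also lost a call (Schwann cell, cell division) and 2 gained one (mitochondrially encoded). The count of higher genes, 0, became 1 (Crygn) with a pseudocount of 5, the nerve score covariate and protein-coding genes alone. It was 0 to 2 when single libraries were left out (1 without wild type replicate 2, 2 without wild type replicate 3). Crygn passed in 4 of 20 alternatives (adjusted p from 0.0113 to 0.984). The count of lower genes, 2, was 3 with the nerve score covariate and 0 with limma without the trend, no filter and the sex make-up covariate. It was 1 with median-ratio scaling, upper-quartile scaling, a pseudocount of 5, haemoglobin and mitochondrial genes removed, the length trend removed, protein-coding genes only and a change of at least 2-fold, and ranged from 0 to 2 when single libraries were left out. Plscr5 stayed lower in 20 of 20 alternatives (log2 fold change -1.47 to -0.86) and passed in 0 (adjusted p from 0.0881 to 1). Against 7 lists passing camera, 4 passed with the nerve score covariate (of the 7 only hair bundle). With protein-coding genes only 11 passed (all 7), and 0 with an estimated correlation or with directional fry. Leaving out single libraries gave 6 to 12 (12 without knockout replicate 2 or 3). The hair bundle list passed at the preset correlation in 20 of 20 alternatives (median -0.20 to -0.13, adjusted p from 1.34e-08 to 0.00415). Beyond the fewer features or libraries of a setting, the cause was not tested. The share of passing genes near Plscr5 was 0 wherever one had a position, also in windows of 5 and 20 Mb.

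When single libraries were left out, Plscr3 ranged from -0.086 to 0.12, Plscr1 from -0.030 to 0.11, Plscr4 from -0.026 to 0.077, mt-Co3 from -0.10 to 1.11 and the mitochondrially encoded list median from -0.052 to 0.085, the list negative without replicate 2 or 3 of either genotype and the genes without wild type replicate 1, knockout replicate 3, knockout replicate 2 and wild type replicate 3. With the nerve score covariate Spp1 was -0.026, Tmem63c -0.012, mt-Co3 -0.42, the cell division median -0.12 and the mitochondrially encoded median -0.00087. The Schwann cell median, -0.0201, came near 0 because the score holds these genes. With the sex make-up covariate the scramblase and flippase median was 0.0037 and the mitochondrially encoded median -0.074. The cause of other sign changes was not tested.

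The deviations of same-numbered libraries correlated across genes at 0.19, -0.055 and 0.24, and knockout replicates 1 and 3, but not 2, correlated best with their own number, a hint of pairing, but 1 pair did not deviate together. With the replicate block, 0 genes were higher, 0 lower and 8 lists passed camera, and the Plscr5 log2 fold change was -1.28. DESeq2 and limma-voom need counts and were not run. Library-size scaling equals the deposited values and the stricter filter the main one. Unknown depth limits genes near 1 TPM.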

Other observations

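Tests chosen only after the result was seen were the removal of wild type replicate 3 as a test of the nerve lists (each library left out in turn was set beforehand), the nerve score covariate and the removal of the length trend as settings, the comparison of hair bundle with hair cell identity genes, the count of neighbouring genes, and the splits of the libraries for the nerve lists and the hair bundle list; the genes in this and the next paragraph were also picked after their values were seen. 3 neighbouring genes were all lower in the knockout, with no overlap between groups at any of them. Srl, which encodes a calcium-binding protein of the sarcoplasmic reticulum, stood at 6.08 ± 0.73 TPM in the knockout and 13.2 ± 0.7 TPM in the wild type (log2 fold change -1.01, SE 0.13, limma adjusted p = 0.133). Pam16, a subunit of the mitochondrial import motor, stood at 10.1 ± 3.4 and 20.4 ± 5.5 TPM, and the antisense gene Gm15879 at 4.62 ± 2.12 and 9.67 ± 1.23 TPM (limma adjusted p = 0.989 for both). Robo2, an axon guidance receptor gene, stood at 40.4 ± 1.5 and 53.9 ± 1.0 TPM (log2 fold change -0.41, limma adjusted p = 0.729).

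The log2 ratio of mt-Nd4l to the overlapping mt-Nd4 was -2.54 ± 0.10 in the knockout and -1.85 ± 0.10 in the wild type (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). The libraries differed in sex make-up: knockout replicate 2 had 357 TPM of Xist and 0.24 TPM over 4 Y-linked genes, wild type replicate 2 had 0.16 and 148 TPM, and the other 4 libraries held both. Each of those 4 libraries therefore probably pooled animals of both sexes, which the labels do not state. Pou4f3, the transcription factor named in the extraction text, stood at 32.9 ± 2.5 TPM in the knockout and 36.0 ± 2.0 TPM in the wild type (log2 fold change -0.13, SE 0.09).

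The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2 genes past the threshold, 5 of the 10 splits gave as many, and the highest of the others gave 8. It gave 7 lists past camera at the preset correlation, 8 of the 10 splits gave as many, and the highest of the others gave 10. The split with 8 genes set knockout replicate 1 and wild type replicates 1 and 2 against the rest and had 880 genes at an unadjusted p under 0.01, against 102 in the real split. That points to a structure among the libraries that does not follow genotype. The first principal component, with 33.5% of the variance, orders them the same way, from -27.82 in knockout replicate 1 to 40.23 in wild type replicate 3.

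The higher neuronal and Schwann cell lists had a median log2 fold change of 0.64 over their 47 genes. A candidate explanation is 1 wild-type library with less nerve tissue. Without wild type replicate 3 the median was 0.214, but that library had been seen to be low in these genes first, so a smaller median had to follow and the explanation stays open. The scaling of the deposited values to a constant total is argued against, since median-ratio scaling left the median at 0.655. Of 10 splits 2 gave a median as far from 0, with 0.643 in the real split and 0.702 in the highest of the others, too few splits to weigh chance. A difference in nerve content between the genotypes stays open, and camera does not decide it. Both lists stayed past camera at the preset correlation without that library. That preset is far below the inter-gene correlations estimated over all libraries, 0.61 for neuronal and 0.59 for Schwann cell genes. With these estimates neither list passed camera (adjusted p = 0.571 for both).

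The lower hair bundle list had a median of -0.163. A trend with transcript length and dilution by nerve tissue are argued against as its whole cause, since the median was -0.153 with the length trend removed and -0.144 with the nerve score as a covariate. Fewer hair cells stays open: exchanging genes between this list and the identity genes gave p = 0.00532 for the difference of their medians (-0.10) in a permutation test that takes genes as independent, and the difference was -0.12 both without wild type replicate 3 and with the nerve score, but it lies within the spread of the identity genes (SD 0.223, or 0.135 without Pvalb and Calb2), and 5 of these 23 genes were as low as the bundle median. Per library, the bundle median minus the identity median, each relative to the mean of all libraries, lay between -0.06 and -0.02 in the 3 knockout and between 0.04 and 0.12 in the 3 wild-type libraries, with an exact permutation p of 0.1, the smallest possible. In 1 of 10 splits, the real one, the median was this far from 0, with 0.158 as the highest of the others, too few splits to weigh chance, and 3 of 9 other splits also took this list past camera; no biological explanation was tested beyond the number of hair cells.

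Processed pseudogenes made up 17.6% of the 102 features at an unadjusted p under 0.01, though 463 of the 17097 tested features are of that kind. Unstable estimates for pseudogenes could produce this without any effect of genotype: in 2 of 9 other splits their share was at least as large, with 20.3% as the highest. That count lies between the bounds set, so this prediction decides nothing. The shares in the 9 other splits were 9.84, 13.85, 19.7, 14.29, 12.87, 20.27, 2.27, 15.38 and 9.28%. A raised share is therefore not particular to the split by genotype, and its cause was not settled. Linked segments that differ between the genotypes are argued against as the source of these features as a set, since 6 pairs lay within 1 Mb of each other where random draws of as many genes gave a median of 7. A single segment such as that of Srl and Pam16, which made 3 of the 6 pairs, is not excluded.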
